A study of Homo sapiens with 18 samples.

How the data were processed

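RNA was measured in 18 samples of HL60 cells with Affymetrix expression arrays. The samples are 9 sucrose density gradient fractions, numbered 3 to 11, of control cells and the same 9 fractions of cells after 72 h with VitD3, with 1 array for each treatment and fraction. Per the labels' protocols, RNA was extracted from each fraction with Trizol, treated with DNase, purified on columns and labelled with biotin. The labels do not say at which end of the gradient fraction 3 lies, how many cultures or gradients were run, or how much RNA each fraction held.

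The deposited values are log2 expression values, 1 per probe set and array, and per the submitters' processing notes they were made with RMA in Affymetrix Expression Console. RMA corrects the background, normalizes arrays by quantiles and summarises probes into probe sets. The versions, the annotation and the genome build are not given in the sources used here, so no coordinates are given. A value compares probe sets within an array after normalization, so a difference between fractions or treatments is relative to the other RNAs of the same fractions, and the total RNA per fraction cannot be recovered from it. The table used here holds 8529 probe sets with values from 1.99 to 14.01. Each of its probe sets reaches at least 5.87 on some array, so RNAs that were dim on all 18 arrays, and the genes measured by them, are not covered. The rule behind that selection is not given in the sources used here.

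Gene names came from the platform annotation supplied with the table. Of the 8529 probe sets, 7413 had 1 gene symbol, 645 had several and 471 had none given. The gene identifiers called for 0 changes of symbol against a RefSeq gene table, which also gave the host genes of snoRNAs (1 measured gene that spans the snoRNA). For each of the 7137 genes with a symbol, the probe set with the highest mean over the 18 arrays was used, and probe sets with several or no symbols were kept as unnamed features, for 8253 features in all. Of the 198 genes with more than 1 probe set, 1 had probe sets called in opposite directions for level. In the table, 136 probe sets had the same values as an earlier probe set, so members of gene families with near-identical sequence are not fully independent.

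All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values), 2-sided, with Benjamini-Hochberg adjustment over the 8253 features and a threshold of 0.05. The level comparison estimated the mean VitD3 minus control difference over the 9 fractions, with the fraction number as a factor. The control slope was the change of the log2 value per fraction number in control cells, in a model with a slope for each treatment over all 18 arrays. The change of slope was the VitD3 slope minus the control slope, with the fraction number as a factor. Each VitD3 fraction was set against the control fraction of the same number. Fractions of a gradient stand in for replicates in these tests. P-values therefore measure the spread over fractions, leave out the spread between cultures, and are too small to speak for cultures.

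A set of 35 gene lists was fixed before the data were examined, and the 29 with at least 5 measured members were tested with limma's camera against all other features, with a preset correlation between genes of 0.01 and again with a correlation estimated per list. P-values of lists were adjusted over the 29 lists within each comparison. Genes named by rank are the 10 largest in each direction among those past the threshold (for level, also with the same sign in all 9 fractions), and CYP24A1, CD14 and VDR. Up to 4 members with the largest estimates are named for a list. Pseudogenes and unnamed loci were passed over. These rules, the tests and most alternatives were fixed before the data were examined.

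The tests were checked on simulated data with 200 of 8253 features changed and the spread of the real arrays. With independent fractions, 88% of log2 level differences of 1 and 25% of those of 0.5 were recovered, with 7 false calls among 120. For the change of slope, 27% of changes of 0.2 per fraction and 2% of changes of 0.1 were recovered, with 3 false calls among 32. For the control slope, the shares were 37% and 4%, with 3 false calls among 44. In the real data, the VitD3 minus control differences of neighbouring fractions were correlated around their mean (lag-1 autocorrelation 0.34) but hardly around their slope (0.011). With an autocorrelation of 0.34 in the simulated level comparison, 16.2% of unchanged features had an unadjusted p below 0.05, and 160 of the 301 calls were false. With the same autocorrelation around the slope, 49 of 123 calls of a changed slope and 105 of 166 calls of a control slope were false. Given the downward bias, the 0.011 does not show that fractions were independent around the slope, and 0.34 may be too mild for level. For the control slope no autocorrelation was measured.

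The alternatives were quantile normalization of the table again, centring of each array on its brighter probe sets, only features above the median level, only features with a symbol, a prior variance that follows the level, the mean of a gene's probe sets, leaving out each fraction in turn or fractions 3 and 11 together, models without the fraction, an offset of 1 between the fraction numbers of the treatments, a minimum log2 difference of 0.5, a quadratic term, and means of fractions 8 to 11 minus fractions 3 to 6. As arrays carry no read depth, their number limits the precision.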

Results

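RNA levels were measured in fractions of sucrose density gradients from HL60 cells, an established human promyeloblast line derived from acute myeloid leukaemia, which mature towards monocytes when given vitamin D3. A sucrose gradient separates RNAs by the size of the particles they sediment with, from free RNA through ribosomal subunits to mRNAs loaded with many ribosomes. The 18 arrays comprised 9 fractions, numbered 3 to 11, of control cells and 9 of cells after 72 h with VitD3. Median values per array ranged from 6.42 to 7.14 (log2). They stepped up between fractions 6 and 7 in control cells (6.59 and 6.91) and between fractions 7 and 8 in VitD3 cells (6.77 and 7.10). Neighbouring fractions of a treatment correlated at 0.895 to 0.983 across features, and fractions 3 and 11 at 0.518 in control and 0.598 in VitD3 cells. The same fraction of both treatments correlated at 0.744 to 0.866.

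The first comparison asked which RNAs were higher or lower in VitD3 cells on average over fractions 3 to 11, each fraction counted alike. As the RNA amount of each fraction is not known, these differences are not those of whole cells. CYP24A1, the vitamin D catabolic enzyme and a classical target of the vitamin D receptor, rose from a mean of 2.86 to 11.07 (log2) (8.20 ± 0.35, SD over fractions, n = 9, adjusted p = 2.16e-15). The acute-phase proteins HP, ORM1 and ORM2 rose by 7.92 ± 0.55, 7.74 ± 0.71 and 7.54 ± 0.81, and the water and glycerol channel AQP9 by 7.30 ± 0.97. The monocyte lipopolysaccharide co-receptor CD14 rose by 7.21 (± 0.82, adjusted p = 2.77e-12). The receptor TREM1, which amplifies myeloid activation, rose by 7.10 ± 0.68, the calcium-binding alarmin S100A8 by 6.35 ± 0.36, the carboxylesterase CES1 by 6.10 ± 0.55 and the short-chain fatty acid receptor FFAR2 by 5.85 ± 0.47. Each of these 10 genes was higher in 9 of 9 fractions. The control means of all but CES1 (6.14) lay below the lower quartiles of the control arrays (5.48 to 6.21), where arrays compress differences, so no exact fold is given.

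The largest falls were those of ITM2A, a membrane protein (-3.59 ± 0.70, adjusted p = 1.68e-09), and PRTN3, the azurophil granule protease proteinase 3 (-3.48 ± 0.60). CA8, a carbonic anhydrase-related protein, fell by 3.20 on the log2 scale, the membrane protein MLC1 by 3.10, the E2F partner TFDP2 by 3.09 and the surrogate light chain gene IGLL1 by 3.05. The lipid synthesis genes ACAT2, SCD and HMGCS1 fell by 3.00, 2.96 and 2.86, and the granule protein gene PRG2 by 2.96. All 10 were lower in 9 of 9 fractions. VDR, the vitamin D receptor itself, was 0.49 ± 0.56 higher (adjusted p = 0.0261, higher in 7 of 9 fractions), and this call was lost without fraction 4, 5, 6 or 11 (adjusted p = 0.0546, 0.0718, 0.0621 and 0.0657) and after quantile normalization (0.28, adjusted p = 0.129). It was also lost without the fraction in the model (adjusted p = 0.446) and against the control fraction 1 number higher (0.19, adjusted p = 0.540).

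**Figure D1:**
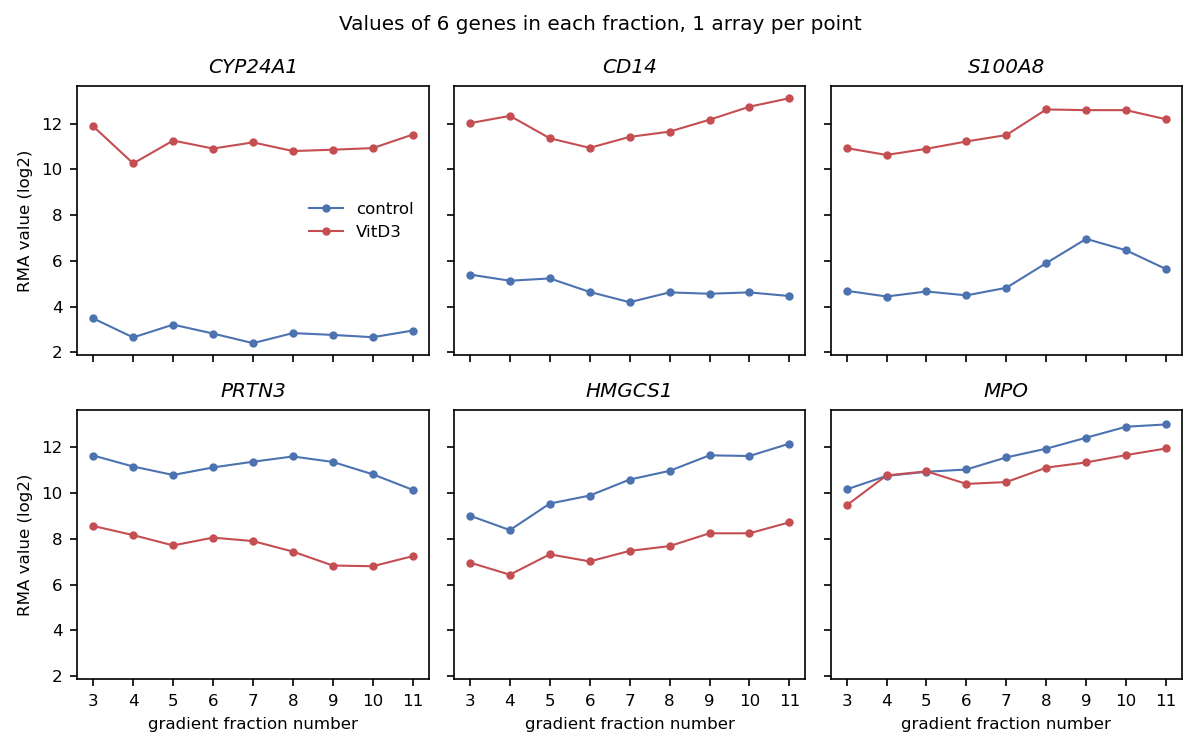
Values of 6 genes (log2, vertical axis) in each gradient fraction (horizontal axis), with 1 array per point, control in blue and VitD3 in red. CYP24A1, CD14 and S100A8 lie above control in 9 of 9 fractions, PRTN3 and HMGCS1 below it in 9 of 9, and MPO, shown as a further promyelocyte granule gene chosen after its values were seen, below it in 7 of 9.

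Among the 8253 features, 854 were at least 2-fold higher in VitD3 cells and 503 at least 2-fold lower with an adjusted p below 0.05 and the same sign in 9 of 9 fractions. At any size and sign pattern, 2401 passed as higher and 1975 as lower, 53.0% of all features (2091 and 2492 after quantile normalization), of which 1488 and 990 kept their sign in 9 of 9 fractions. Without the fraction in the model, 1000 and 777 passed. The p-values rest on fractions and not on cultures, so they are too small to speak for cultures. The differences of neighbouring fractions were also correlated around their mean (0.34). Around their slope the value was 0.011, and the fit to 9 fractions biases both values downwards. With 0.34 as noise in simulated data, 16.2% of unchanged features had an unadjusted p below 0.05. The larger counts may therefore hold more false calls than the threshold states. The simulation changed 200 of 8253 features, so its share of false calls (160 of 301) does not carry over to these counts.

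The largest list medians were those of vitamin D receptor targets (3.72), inflammatory genes (2.83), monocyte markers (2.55) and neutrophil markers (2.54), and the lowest those of cholesterol synthesis (-1.65) and promyelocyte genes (-1.26). Of 14 measured vitamin D receptor targets, 13 rose and 1, the Wnt co-receptor LRP5, fell, with the antimicrobial peptide gene CAMP at 4.09 ± 0.89 (camera adjusted p = 3.51e-11). All 18 measured monocyte and macrophage markers rose, among them S100A9 (5.40 ± 1.01) and S100A12 (4.94 ± 1.03), with a list median of 2.55 (adjusted p = 3.38e-13). CD14 belongs to both lists. Of 17 inflammatory cytokine and NF-kB target genes, 17 rose, led by the chemokines CCL3 (5.42 ± 0.93), CXCL8 (4.84 ± 0.69) and CCL4 (4.47 ± 0.85) and the cytokine IL1B (4.42 ± 0.84) (adjusted p = 1.90e-12). Of 8 neutrophil maturation markers, 7 rose, including ORM1, the formyl peptide receptors FPR2 (4.08 ± 0.60) and FPR1 (3.90 ± 0.58) and PADI4 (2.94 ± 0.68), while the granule protein BPI was at 0.04 ± 1.22 (list adjusted p = 4.88e-06). Of 17 promyelocyte granule and progenitor genes, 15 fell and 0 rose, with PRTN3 and PRG2 followed by NUCB2 (-2.39 ± 0.68) and the receptor kinase FLT3 (-2.09 ± 1.06) (adjusted p = 5.05e-08). Of 17 cholesterol synthesis genes, 16 fell, led by HMGCS1, the sterol oxidase MSMO1 (-2.59 ± 0.95), the reductase DHCR7 (-2.50 ± 0.81) and the cyclase LSS (-2.45 ± 1.08) (adjusted p = 1.59e-10). Adjusted over the list alone, the counts of these 6 lists were the same. With an estimated correlation their adjusted p were 0.00571, 0.00844, 0.0123, 0.0123, 0.0387 and 0.0392 in the order given, and they were the only 6 of 29 lists that passed with it. The table held 14 of the 22 vitamin D receptor targets fixed and 17 of 25 inflammatory genes. It held 18 of 36 monocyte markers and 8 of 24 neutrophil markers. A gene dim in all control arrays entered the table only where a VitD3 array reached at least 5.87. The counts of rises, medians and p-values of these lists thus partly reflect that selection. The reverse holds for genes dim in VitD3 cells.

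A further 8 lists passed camera with the preset correlation alone. Of 26 ribosome biogenesis genes, 21 fell and 0 rose, with LYAR at -1.77 ± 0.49 and RRP9 at -1.68 ± 0.77 (adjusted p = 2.00e-07, and adjusted p = 0.350 with an estimated correlation). Of 73 small nucleolar and Cajal body RNAs, 48 fell and 2 rose, with a median of -0.61 (adjusted p = 6.82e-10, and adjusted p = 0.248 with an estimated correlation). The largest falls were those of SNORD75 (-2.40 ± 0.63), SNORD74 (-1.97 ± 0.46), SNORD78 (-1.84 ± 0.85) and SNORD60 (-1.70 ± 0.59). Of 27 DNA replication genes, 17 fell and 1 rose, with POLE2 at -1.44 ± 0.53 and RFC4 at -1.13 ± 0.76 (adjusted p = 0.000459, and adjusted p = 0.412 with an estimated correlation). Of 17 glycolysis genes, 11 fell and 1 rose, where ALDOC (-2.74 ± 0.68) and LDHA (-2.06 ± 0.80) were lowest and the glucose transporter SLC2A3 (2.22 ± 0.44) rose while SLC2A1 (-1.53 ± 0.66) fell (adjusted p = 0.00733, and adjusted p = 0.574 with an estimated correlation). Of 28 proteasome genes, 11 fell and 0 rose, led by PSMB3 (-1.58 ± 0.99) and PSMA3 (-1.46 ± 0.57) (adjusted p = 0.00116, and adjusted p = 0.555 with an estimated correlation). Of 57 cytosolic ribosomal protein genes, 10 fell and 0 rose, with RPL13 at -0.99 ± 0.53 and a median of -0.24 (adjusted p = 0.000706, and adjusted p = 0.774 with an estimated correlation). That call was lost against the control fraction 1 number higher (median -0.03, adjusted p = 0.314) and in fractions 3 to 7 alone, a choice made after the data were seen (-0.01, adjusted p = 0.456). Of 27 lysosomal genes, 18 rose and 2 fell, with the cathepsins CTSD (2.89 ± 0.48) and CTSZ (2.63 ± 0.49) highest (adjusted p = 6.51e-06, and adjusted p = 0.350 with an estimated correlation). Of 11 immediate early genes, 6 rose and 1 fell, including FOS (1.99 ± 0.76), JUNB (1.89 ± 0.59) and EGR1 (1.87 ± 0.86) (adjusted p = 0.0296, and adjusted p = 0.571 with an estimated correlation). That call was lost above the median level (median 0.22, adjusted p = 0.338), without fractions 3 and 11 (0.0743) and against the control fraction 1 number lower (0.0731). The glycolysis call was lost above the median level (0.104). In fractions 3 to 7 alone the calls of glycolysis (0.0836) and DNA replication (0.0575) were lost, and in fractions 8 to 11 alone that of the immediate early genes (0.0916). Adjusted over the list alone, the counts of falls were 23 for ribosome biogenesis, 51 for the snoRNAs, 12 for glycolysis, 10 for the proteasome and 9 for ribosomal proteins, 2 glycolysis genes rose, and the other lists kept the counts given.

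**Figure D2:**
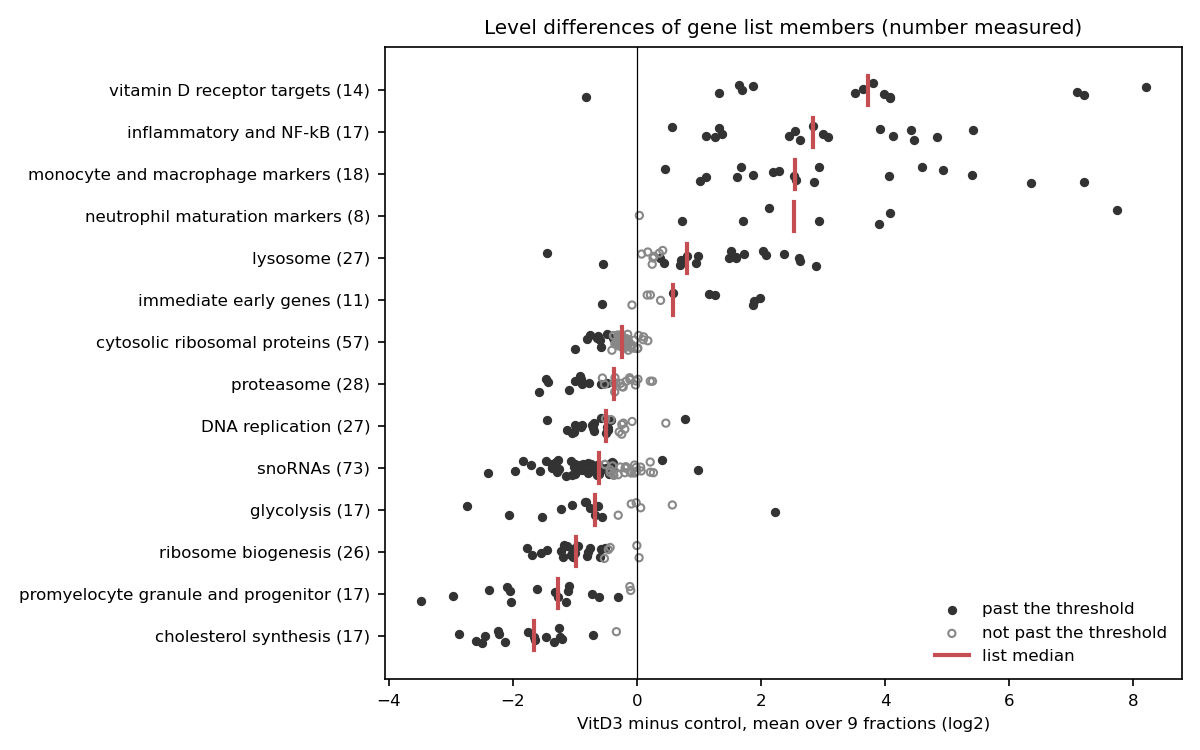
Level differences (VitD3 minus control, mean over 9 fractions, log2, horizontal axis) of the members of the 14 gene lists that passed camera with the preset correlation, 1 point per gene, filled where the gene passed the threshold, with the list median as a red bar. The medians range from 3.72 for vitamin D receptor targets to -1.65 for cholesterol synthesis.

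The cell cycle list moved in both directions. Of 29 genes, 5 rose and 5 fell (3 and 5 adjusted over the list alone, list adjusted p = 0.449), and the proliferation marker MKI67 (1.31 ± 0.60) and the ribonucleotide reductase subunit RRM2 (0.96 ± 0.59) rose while CDC6 (-0.78 ± 0.89) and AURKB (-0.76 ± 0.46) fell. The 23 unfolded protein and integrated stress response genes also divided. PPP1R15A (1.98 ± 0.79) led 11 that rose, and the serine synthesis enzyme PHGDH (-1.60 ± 0.85) led 8 that fell (list adjusted p = 0.974, with a median of 0.40 and a mean of 0.08). Of 19 aminoacyl-tRNA synthetases, 5 fell, led by FARSA (-1.95 ± 0.82), and 3 rose, led by SARS1 (1.23 ± 0.58). Of 18 microRNA pathway genes, 4 rose, with AGO4 at 1.63 ± 0.70, and 4 fell, with PRKRA at -1.32 ± 0.37 and XPO5 at -1.23 ± 0.74. Of 34 RNA-binding regulators, 8 rose, among them CPEB4 (1.52 ± 0.91) and the mRNA decay factor ZFP36 (1.48 ± 0.49), and 5 fell, among them YBX3 (-0.85 ± 0.73). Of 10 class I antigen presentation genes, 6 rose, with the peptide transporter TAP1 at 1.79 ± 0.49, and 1 fell, CALR at -1.10 ± 0.68. Of 5 interferon response genes, 3 rose, with RSAD2 at 2.54 ± 1.09. Of 39 replication-dependent histone genes, 11 rose, with H2BC12 at 2.26 ± 1.46, and 5 fell. In the respiratory chain 4 rose and 11 fell of 37 (4 and 7 adjusted over the list alone), and in the spliceosome 3 rose and 9 fell of 33. Among long coding sequences 8 rose and 6 fell of 25, and among small coding sequences 7 and 11 of 33. Of the non-coding RNAs 2 rose and 4 fell of 9. Of other initiation factors 7 rose and 4 fell of 28, and of translation factors with oligopyrimidine mRNAs 0 and 3 of 17. The latter list was fixed with VIM, HNRNPA1 and NAP1L1 in it, whose products are not translation factors. None of the lists in this paragraph passed camera for level. Among the lists with fewer than 5 measured members, the NADPH oxidase subunit CYBB rose by 4.54 ± 0.53, RAC2 by 0.90 ± 0.93 and NCF4 by 0.81 ± 0.61. CYBA did not pass (0.23 ± 0.28, adjusted p = 0.137). Of the iron genes, the transferrin receptor TFRC fell (-2.52 ± 0.82). The ferritin light chain FTL (1.13 ± 0.44) and the metal transporters SLC11A1 (2.03 ± 0.42) and SLC11A2 (0.64 ± 0.42) rose. The only lymphoid marker in the table was NKG7 (0.53 ± 0.52, adjusted p = 0.0129), and the erythroid, class II antigen presentation and mitochondrial mRNA lists had 0 measured members. For SLC11A1, CAMP, S100A9, S100A12, FPR1, FPR2, PADI4, CCL3, CCL4, IL1B, RSAD2, AGO4, CPEB4 and VDR, too, the control mean lay below 5.48, the smallest lower quartile of any array. For CA8, FLT3, POLE2, LYAR, ALDOC, LSS, LRP5 and SNORD75 the VitD3 mean did. The sizes of these differences are not exact either.

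The second comparison described how RNAs were spread over the gradient in control cells, as the change of the log2 value per fraction number. A positive slope means that an RNA took a larger part of the array signal in fractions with higher numbers. The RNAs that leaned most to high numbers were those of the poly(ADP-ribose) polymerase PARP1 (0.72 ± 0.09, SE), the RNA helicase DDX3X (0.69 ± 0.06), the cell cycle genes CCND2 (0.68) and CDK6 (0.68), and the RNA polymerase subunit POLR2B (0.67). They were followed by the chaperone HSP90AA1 (0.65), the spliceosome helicase SNRNP200 (0.64), the segregase VCP (0.63), DDX23 (0.63) and the long non-coding RNA TUG1 (0.64). The RNAs that leaned most to low numbers were the non-coding RNAs RMRP (-0.58 ± 0.06) and RPPH1 (-0.58 ± 0.08), the RNA parts of the ribonucleases MRP and P. The Cajal body RNA SCARNA10 (-0.50) followed, with the mRNAs of STARD3NL (-0.55), SMIM20 (-0.54), NTAN1 (-0.52), GTF2A2 (-0.51), DNAJC19 (-0.49), SLC25A33 (-0.49) and CISD2 (-0.49). In all, 3044 features had a positive and 1634 a negative slope past the threshold, against 2178 and 2476 after the arrays were quantile normalized again, so the balance between the directions differed with the scaling. In VitD3 cells, 2412 slopes were positive and 1292 negative, and 2011 features were positive and 961 negative in both treatments.

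By list, most long and small coding sequences had slopes of opposite sign, though no length was measured here. All 25 genes with long coding sequences had positive slopes, with a median of 0.34, led by DOCK2 (0.55 ± 0.08) and PRKDC (0.52 ± 0.11) (camera adjusted p = 1.76e-05, and adjusted p = 0.538 with an estimated correlation). Of 33 genes with small coding sequences, 19 had negative and 2 positive slopes, with TIMM9 at -0.48 ± 0.06 and POLR2K at -0.40 ± 0.08 (adjusted p = 7.04e-06, and adjusted p = 0.447 with an estimated correlation). Of 57 ribosomal protein genes, 27 had negative and 0 positive slopes, with RPL17 at -0.28 ± 0.05 (adjusted p = 3.45e-08, and adjusted p = 0.447 with an estimated correlation). Of 73 snoRNAs and Cajal body RNAs, 34 had negative slopes and 1 a positive slope, that of SNORD59B (0.42 ± 0.15), dim in control cells as SCARNA10 was (adjusted p = 5.16e-07, and adjusted p = 0.447 with an estimated correlation). Of 37 respiratory chain genes, 13 were negative and 2 positive (adjusted p = 0.000169, and adjusted p = 0.540 with an estimated correlation). Of 9 non-coding RNAs, 6 were negative, while TUG1 and the nuclear RNA MALAT1 (0.56 ± 0.14) were positive (adjusted p = 0.0132, and adjusted p = 0.369 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases, 18 were positive, led by EPRS1 (0.60 ± 0.07) and NARS1 (0.58 ± 0.05) (adjusted p = 1.94e-06, and adjusted p = 0.366 with an estimated correlation). Of 26 ribosome biogenesis genes, 19 were positive, led by NCL (0.59 ± 0.06), and 1 was negative (adjusted p = 0.000119, and adjusted p = 0.366 with an estimated correlation). Positive slopes were also passed by 23 of 29 cell cycle genes, 18 of 27 DNA replication genes, 20 of 33 spliceosome genes, 21 of 34 RNA-binding regulators, 17 of 28 other initiation factors, 16 of 27 lysosomal genes and 9 of 17 glycolysis genes. In that order, their adjusted p were 0.00145, 0.00378, 0.00847, 0.00808, 0.00808, 0.0222 and 0.0363. With an estimated correlation they were adjusted p = 0.447, 0.447, 0.366, 0.366, 0.371, 0.538 and 0.540. Negative slopes in these lists numbered 0, 2, 2, 2, 1, 3 and 0. The calls of cell cycle genes and non-coding RNAs were lost above the median level (adjusted p = 0.0524 for both), and that of the non-coding RNAs with means of fractions in place of slopes (0.0565). Without fractions 3 and 11, those of lysosome (0.0566) and glycolysis (0.0580) were lost. The glycolysis call was also lost without fraction 5 (0.0534) or 10 (0.0531) and with named features alone (0.0510). In total 15 of 29 lists passed with the preset correlation and 0 with an estimated one. The lists of myeloid markers and vitamin D receptor targets were not among them. The labels do not say which end of the gradient fraction 3 is.

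The third comparison asked which RNAs shifted along the gradient between treatments, as the VitD3 slope minus the control slope. The largest positive changes were those of MGAM, a brush-border glucosidase also made by granulocytes (0.46 ± 0.05, SE, adjusted p = 0.000118), the membrane adaptor PAG1 (0.46 ± 0.08), KCTD12 (0.45 ± 0.05), the histone gene H2BC12 (0.44 ± 0.08) and the endocytic receptor LRP1 (0.44 ± 0.05). Next came FRMD3 (0.44), PDCD10 (0.44), the growth factor BMP6 (0.43), MLF2 (0.41) and the C-type lectin CLEC6A (0.40). Shifts to lower numbers were largest for NXF3 (-0.45 ± 0.04, adjusted p = 5.68e-05), the replicative helicase subunit MCM7 (-0.45 ± 0.04), the nuclear import factor KPNA2 (-0.44 ± 0.05), the mitotic kinase PLK1 (-0.44 ± 0.05), and the granule protein BPI (-0.42 ± 0.05). Next came the folate enzyme MTHFD1 (-0.40), DPF2 (-0.40), the splicing factors SF3A3 (-0.38) and RBM22 (-0.38), and IFT122 (-0.38). MCM7 went from a slope of 0.48 in control to 0.03 in VitD3 cells, and PLK1 from 0.38 to -0.07. Against the control fraction 1 number lower, the calls of PAG1, KPNA2, BPI, MTHFD1, DPF2 and SF3A3 were lost, and against the fraction 1 number higher that of H2BC12. The control means of MGAM, PAG1, LRP1, FRMD3, BMP6 and CLEC6A and the VitD3 means of MTHFD1 and IFT122 lay below 5.48, so 1 of the 2 slopes compared is that of a dim signal and their changes cannot be read as shifts along the gradient. Without the fraction in the model the calls of PAG1, KPNA2, BPI, MTHFD1, DPF2, SF3A3, H2BC12, PDCD10 and RBM22 were lost.

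In all, 708 features shifted to higher and 1259 to lower fraction numbers, against 877 and 973 after the arrays were quantile normalized again. Among the 7077 features with both treatment means above 5.48, a choice made after the data were seen, 589 and 1119 passed. Slopes had an SD over features of 0.22 in control and 0.19 in VitD3 cells, and correlated at 0.826 (over features, which are not independent replicates). The counts depended on how fractions were set against each other. With each VitD3 fraction set against the control fraction 1 number lower, 79 and 144 passed, and against the fraction 1 number higher, 436 and 662. Without fraction 10, 324 and 638 passed, and without fraction 4 or 9 the shifts to higher numbers were 425 and 426. A model without the fraction gave 17 and 21. VitD3 fraction 7 correlated best with control fraction 6 (0.558, against 0.459 with control fraction 7), and the other 8 fractions with the control fraction of their own number.

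**Figure D3:**
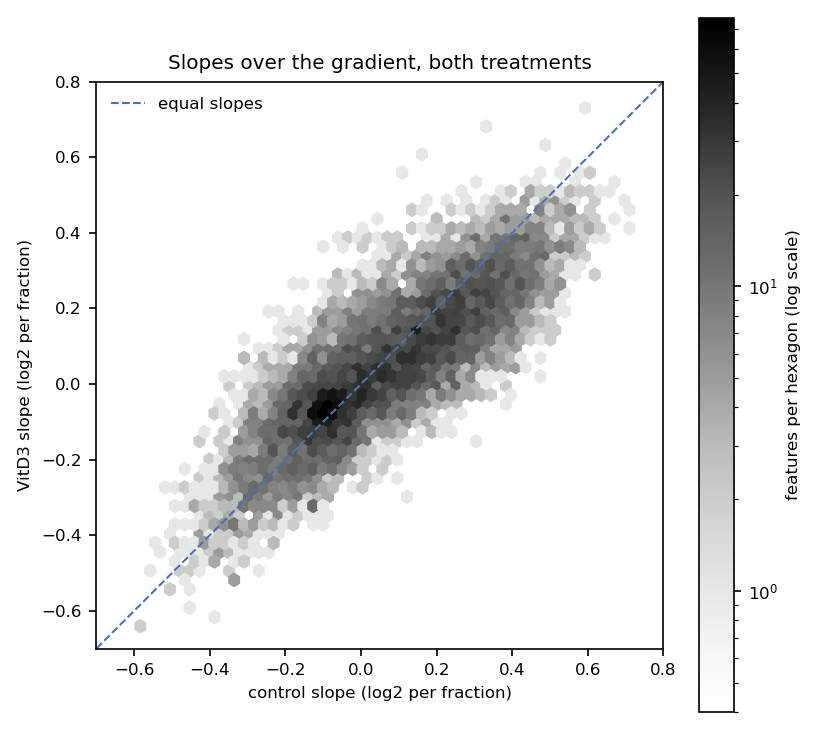
Slopes over the gradient in control (horizontal axis) and VitD3 cells (vertical axis), both in log2 per fraction number, for 8253 features, shaded by the number of features per hexagon. The dashed blue line marks equal slopes, and the correlation is 0.826.

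By list, 12 lists passed camera with a direction to lower fraction numbers, among them aminoacyl-tRNA synthetases and ribosome biogenesis genes. Of 19 aminoacyl-tRNA synthetases, 17 shifted to lower and 0 to higher numbers, with FARSB (-0.35 ± 0.04), VARS1 (-0.34 ± 0.05) and KARS1 (-0.33 ± 0.05) first (camera adjusted p = 1.26e-09, and adjusted p = 0.0959 with an estimated correlation). Of 26 ribosome biogenesis genes, 19 shifted to lower numbers, with PES1 (-0.36 ± 0.05) and the dim UTP20 (-0.32 ± 0.05) first (adjusted p = 1.93e-07, and adjusted p = 0.0959 with an estimated correlation). Of the 17 genes listed as translation factors with oligopyrimidine mRNAs, 8 did, including PABPC1 (-0.27 ± 0.05) and EIF4B (-0.26 ± 0.05) (adjusted p = 0.000339, and adjusted p = 0.392 with an estimated correlation). Of 57 ribosomal protein genes 7 did (2 adjusted over the list alone), with RPL12 at -0.19 ± 0.05 (adjusted p = 0.000379, and adjusted p = 0.543 with an estimated correlation). Shifts to lower numbers were also passed by 11 of 29 cell cycle genes, 14 of 27 DNA replication genes, 15 of 33 spliceosome genes, 8 of 28 other initiation factors, 11 of 34 RNA-binding regulators, 7 of 17 glycolysis genes, 7 of 27 lysosomal genes and 9 of 25 long coding sequences. In that order, their adjusted p were 2.94e-05, 0.000339, 0.00708, 0.00709, 0.00708, 0.00321, 0.0252 and 0.00145. With an estimated correlation they were adjusted p = 0.323, 0.323, 0.360, 0.325, 0.454, 0.484, 0.543 and 0.514. Shifts to higher numbers in these lists numbered 0, 0, 2, 0, 1, 0, 1 and 0. Against the control fraction 1 number lower, the median of the long coding sequences turned from -0.11 to 0.03, and the calls of cell cycle genes (adjusted p = 0.124), other initiation factors (0.132) and RNA-binding regulators (0.0615) were lost. The call of other initiation factors was also lost among features above the median level (0.0799). The lysosomal call was lost after quantile normalization (0.130), above the median level (0.0741), without fraction 5 (0.0649) and against the control fraction 1 number higher (0.107). With the common line of VitD3 on control slopes taken away, a choice made after the data were seen, 5 of these calls were lost: spliceosome (0.142), other initiation factors (0.204), RNA-binding regulators (0.197), lysosome (0.202) and long coding sequences (median -0.01, 0.696).

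A further 6 lists passed camera with a direction to higher fraction numbers. Of 33 small coding sequences, 14 shifted to higher and 0 to lower numbers, with POLR2K (0.33 ± 0.07) and the proteasome assembly factor POMP (0.31 ± 0.06) first (adjusted p = 1.41e-08, and adjusted p = 0.323 with an estimated correlation). Of 37 respiratory chain genes, 12 shifted to higher and 1 to lower numbers, led by UQCR10 (0.34 ± 0.06) and COX6C (0.34 ± 0.06) (adjusted p = 6.99e-08, and adjusted p = 0.323 with an estimated correlation). Of 5 interferon response genes, 4 had a positive change past the threshold, led by RSAD2 (0.36 ± 0.06), which was dim in control cells (adjusted p = 0.000396, and adjusted p = 0.0959 with an estimated correlation). Of 39 histone genes, 5 did (adjusted p = 0.000662, and adjusted p = 0.579 with an estimated correlation). Of 17 inflammatory genes 6 did and 1 shifted to lower numbers, with TNFAIP2 at 0.33 ± 0.07 (adjusted p = 0.00904, and adjusted p = 0.325 with an estimated correlation), and of 18 monocyte and macrophage markers 3 had a positive change past the threshold, namely S100A12 (0.34 ± 0.06), S100A9 (0.28 ± 0.07) and CD14 (0.24 ± 0.06) (adjusted p = 0.00904, and adjusted p = 0.153 with an estimated correlation). These 3 were dim in control cells, and with the 8 members whose means lay above 5.48 in both treatments the list median was -0.01 (adjusted p = 0.401), so no shift of monocyte markers along the gradient is shown. The call of the monocyte list was also lost without fraction 3 (adjusted p = 0.0828), without fractions 3 and 11 (0.0974), above the median level (0.0525) and against the control fraction 1 number higher (0.107). That of the inflammatory list was lost in the last of these settings (median 0.01, adjusted p = 0.270) and without fractions 3 and 11 (0.0782). With the 10 inflammatory genes whose means lay above 5.48 in both treatments the list median was 0.15 (adjusted p = 0.00285). In total 18 of 29 lists passed with the preset correlation and 0 with an estimated one. After quantile normalization 21 passed with the preset correlation. Gained were vitamin D receptor targets (median 0.15, adjusted p = 0.00421), promyelocyte genes (-0.12, 0.00918), cholesterol synthesis (-0.08, 0.0461) and snoRNAs (-0.05, 0.00318). Vitamin D receptor targets also passed above the median level (0.0342), but not with the 5 members bright in both treatments (median 0.04, adjusted p = 0.626). Adjusted over the list alone, 18 aminoacyl-tRNA synthetases and 21 ribosome biogenesis genes shifted to lower numbers, 18 small coding sequences and 17 respiratory chain genes shifted to higher numbers, and 2 ribosomal protein genes shifted to lower numbers.

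**Figure D4:**
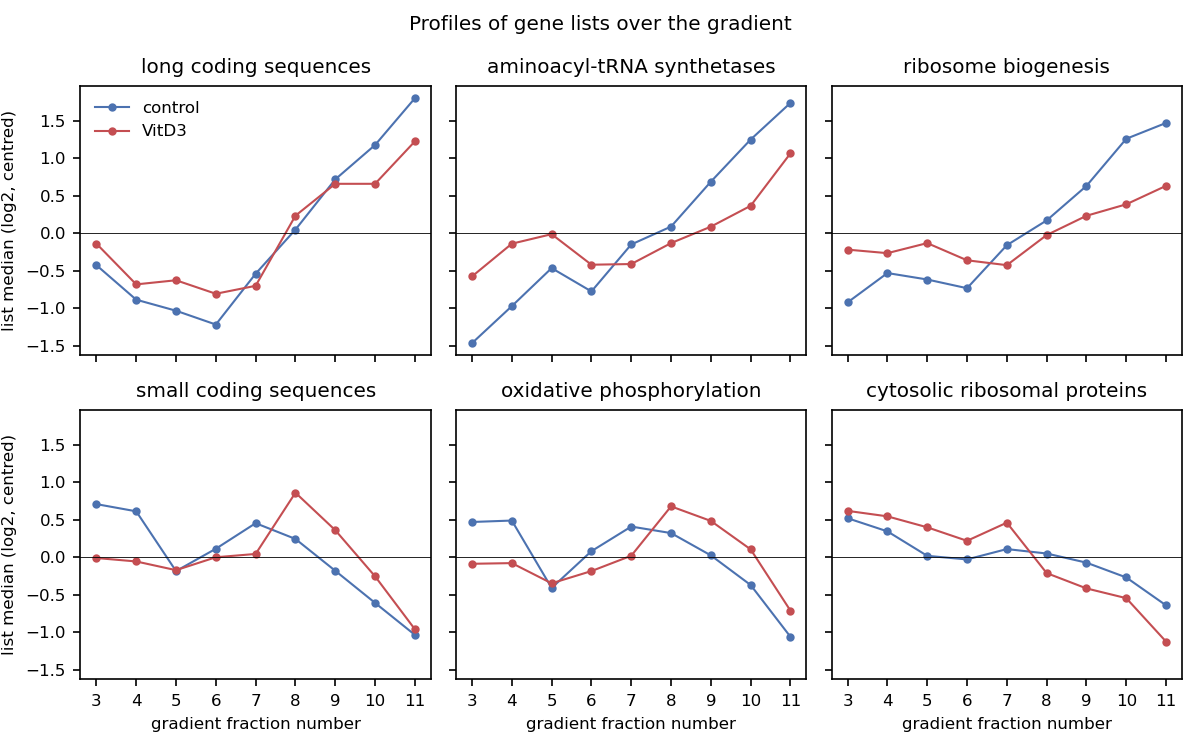
Median values of 6 gene lists (log2, vertical axis, each gene centred on its mean over the 9 fractions of its treatment) in each fraction (horizontal axis), control in blue and VitD3 in red. From fraction 3 to fraction 11 the aminoacyl-tRNA synthetases rise from -1.46 to 1.74 in control and from -0.57 to 1.07 in VitD3 cells.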

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

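The 3 patterns below, the tests on the spread of slopes, on recovery of small nuclear RNAs and on the common line of slopes, and the check on 2 host genes were chosen after the results were seen. The condition that picked the 6 genes of the next paragraph was also written after the data were examined. It asks for a slope past the threshold in both treatments, opposite signs, and a tested difference.

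The slope of GSTM4, a glutathione transferase, went from -0.214 in control to 0.174 in VitD3 cells, a difference of 0.388 (limma, adjusted p = 0.000356). PDCD10 went from -0.238 to 0.199 (0.437, adjusted p = 0.000298), the calcium-binding protein SRI from -0.205 to 0.194 (0.399, adjusted p = 0.000679), and WTAP, a subunit of the RNA methyltransferase complex, from -0.136 to 0.161 (0.297, adjusted p = 0.000966). FARSB, the beta subunit of phenylalanyl-tRNA synthetase, went the other way, from 0.232 to -0.118 (-0.350, adjusted p = 0.000148), as did NXF3, an mRNA export factor paralogue, from 0.296 to -0.158 (-0.454, adjusted p = 5.68e-05). Among 52 groups of 9 values searched for a value far from the others, 0 had one. The groups reuse the same 18 arrays and are not independent. The 5% that chance gives for independent groups is therefore no benchmark for this count.

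Slopes spread less over features in VitD3 than in control cells, with a ratio of SDs of 0.856 (95% interval 0.846 to 0.865, from 1000 bootstrap draws over features). Error in the control slopes would widen their spread. Slopes of odd and even fractions remove error that is independent between fractions, and with them the ratio was 0.850 (0.839 to 0.861). This argues against independent error, while error shared by neighbouring fractions is not removed. An offset of 1 fraction between the gradients would bring the ratio to 1, and it rose to 0.958 (0.946 to 0.971) with VitD3 fractions set against the control fraction 1 number lower, which argues against an offset as the whole source and leaves it open for the larger part. The matched fractions leave out 1 end of each gradient. The ratio over them without an offset was not computed, so the rise cannot be put down to the offset. Array scaling would let quantile normalization restore the ratio, but it gave 0.903 (0.892 to 0.913), which argues against scaling as the whole source. Offset and scaling together, a gradient of another shape, fractions of another volume and a biological change were not told apart, with 1 set of fractions per treatment. The intervals resample features of the same 18 arrays and leave out the spread between gradients.

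The 65 box C/D and H/ACA snoRNAs had a median difference of -0.72 in VitD3 cells, and of the fixed list of 73, which also holds Cajal body RNAs, 48 fell and 2 rose (camera adjusted p = 6.82e-10, and adjusted p = 0.248 with an estimated correlation). An equal loss of all small nuclear RNAs would bring the 19 others as low, but they lay at -0.19, a gap of 0.530 (0.131 to 0.689), which argues against it. The others include the Cajal body RNAs of the fixed list, among them SCARNA10 (-0.19), dim in control cells, where differences are compressed. The interval resamples RNAs as if independent. The estimated correlation of the fixed list was 0.194 for level, so the interval is too narrow. Most snoRNAs are processed from introns of host genes, and a fall of the host mRNAs, a biological explanation, predicts that snoRNAs follow their hosts. Over 27 hosts (median -0.42) of 33 snoRNAs the correlation was 0.421 (permutation p = 0.0287, 100000 permutations), which met the condition written beforehand, a permutation p below 0.05. The rank correlation was 0.256 (permutation p = 0.198), and without the 2 hosts farthest from the median, a check added afterwards, the correlation was 0.10 (permutation p = 0.632). These hosts were CHD8 (0.51) and ATP5F1B (0.42), and their snoRNAs SNORD8 (0.22, not past the threshold) and SNORD59B (0.99) were higher too. Leaving out the extreme hosts narrows the range and by itself lowers a correlation. The relation thus rests on 2 hosts and the test cannot tell. The snoRNAs with the largest falls, SNORD75, SNORD74, SNORD78 and SNORD60, are not among the 33.

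Of 57 ribosomal protein genes, 10 fell in level and 47 did not pass (camera adjusted p = 0.000706, and adjusted p = 0.774 with an estimated correlation). Among all 8253 features, 1975 fell. The median gap of the ribosomal protein genes between fractions 8 to 11 and fractions 3 to 7 was -0.55, against -0.06 for all features. With an offset of 1 fraction between the gradients the gap nearest to 0 was -0.393 (-0.487 to -0.254), which argues against an offset as its whole source. After quantile normalization it was -0.509 (-0.642 to -0.417), which argues against array scaling as its whole source. A general narrowing of slopes would put these genes on the common line of VitD3 on control slopes. They lay -0.126 from it (-0.139 to -0.104). Their median slope went from -0.104 in control to -0.207 in VitD3 cells, away from 0, while a narrowing would bring it nearer to 0. This argues against a narrowing as a source of the gap of these genes in these arrays. The 3 intervals resample the 57 genes as if independent. Their estimated correlation was 0.45 for the change of slope, so the intervals are too narrow. They also leave out the spread between gradients. A biological explanation, such as a move of these mRNAs along the gradient, was not tested apart from offset and scaling.

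Other groupings of the same arrays were also tested, with 100 per comparison including the real one. With treatments swapped within fractions, 1 grouping, the real one, reached the 4376 level calls, and the highest other gave 2070 and differs from it by 1 swapped fraction. With the fraction order shuffled, 1 order, the real one, reached the 1967 calls of a changed slope (highest other 582, an order correlated at 0.75 with the real one), and 1, the real one, the 4678 calls of a control slope (highest other 2851, an order correlated at -0.8 with the real one). Fractions of a treatment may come from 1 culture, and neighbouring fractions are alike, so they are not exchangeable. A steady difference between cultures, or a smooth gradient, would also tend to put the real grouping first. The counts therefore do not speak for chance between cultures.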

How the results depend on the processing

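Of 1276 recomputed values of the genes named by rank or as checks, 1251 kept their direction and side of the threshold, 25 values of 10 genes were no longer past it, and 0 reversed. Genes named by rank were picked as the largest past the threshold in these same arrays. Their share of kept calls therefore does not speak for the other calls. Of 1932 recomputed list results, 1799 kept their side of the threshold, 87 lost a call and 43 gained one. In 3, a list called in the main test had a median of the opposite sign. A list not called in either setting counts as kept whatever its median, so these counts do not measure how stable the medians were. Among features bright in both treatments, chosen after seeing the data, the slope change median of the monocyte markers was -0.007, because members dim in control cells were left out, and 16 lists passed. With each VitD3 fraction set against the control fraction 1 number lower (k-1), the slope change median of the long coding sequences was 0.034; the cause was not tested. The slope in VitD3 cells is the other treatment and not a processing choice: there the respiratory chain median was 0.008, against -0.125 in control (tested as the change of slope, camera adjusted p = 6.99e-08, and adjusted p = 0.323 with an estimated correlation), and 5 lists passed. Restricted to features above the median level, where fewer genes are tested, calls were 1125 higher and 1056 lower for level, 451 and 769 for the change of slope, and 1282 and 991 for the control slope. A minimum log2 difference of 0.5, a stricter test by construction, left 998 and 625 level calls. Without the fraction as a block, level calls were 1000 higher and 777 lower, and slope change calls 17 and 21, because variation between fractions then enters the error. At k+1, 1571 features were higher in level, and slope change calls were 436 and 662; at k-1 they were 79 and 144; the cause was not tested. Leaving out 1 fraction at a time gave 324 to 867 positive and 638 to 1339 negative slope changes; the cause was not tested. Quantile normalization gave 2476 negative control slopes; the cause was not tested. With an estimated correlation, 6 lists passed for level, 0 for the change of slope and 0 for the control slope. Correlated genes alone do not account for this. For the change of slope, the monocyte markers had an estimated correlation of 0.002, below the preset 0.01. Their camera adjusted p was still 0.153 with it. The signal of dim RNAs lies near background on arrays, so their differences are compressed. Lists were also tested on slopes beyond the regression line (16 past) and on level in fractions 3 to 7 (13 past, 2043 and 1495 calls) and 8 to 11 (19 past, 2515 and 2410 calls), which were chosen after seeing the data.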

Other observations

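Gene families outside the fixed lists were grouped by the start of their symbols (83 families of at least 8 measured members), a search chosen after the data were seen. In control cells, 12 of 13 histone lysine demethylases (KDM, median slope 0.34), 18 of 22 DDX and 11 of 12 DHX helicases, 16 of 20 nucleoporins (NUP) and 24 of 30 ubiquitin-specific proteases (USP) had positive slopes past the threshold. USP7 was at 0.62, NUP160 at 0.59 and DDX21 at 0.59. Negative slopes were passed by 6 of 9 LSM proteins (median -0.30), which bind small RNAs, 6 of 9 COMMD proteins and 20 of 47 MRPL proteins of the mitochondrial ribosome, of which 5 were positive. In camera with the preset correlation 14 families passed for the control slope (KDM adjusted p = 0.000824), and 0 with an estimated correlation (KDM adjusted p = 0.491 with an estimated correlation).

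For the change of slope, 11 of 20 nucleoporins shifted to lower fraction numbers in VitD3 cells and 0 to higher (median -0.20, adjusted p = 5.66e-05), with NUP88 at -0.32 and NUP93 at -0.31. Of 39 RAB GTPases, which direct vesicle traffic, 11 shifted to higher and 1 to lower numbers (median 0.12, adjusted p = 2.51e-05), with RAB10 at 0.35 and RAB9A at 0.35. Of 22 DDX helicases, 12 shifted to lower numbers (adjusted p = 0.00049), and of 9 COMMD proteins 5 shifted to higher numbers (adjusted p = 0.00605). With the preset correlation 8 families passed, and 0 with an estimated correlation (adjusted p = 0.773 with an estimated correlation for each). Set against the control fraction 1 number lower, the medians were -0.07 for nucleoporins and 0.05 for RAB GTPases, and against the fraction 1 number higher -0.31 and 0.23. For level, 0 families passed.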
